A study of Homo sapiens with 5 samples.

How the data were processed

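The series measured the enhancer activity of synthetic and control DNA sequences placed into the genome of MEC1, an established B cell line from chronic lymphocytic leukemia. Per the labels and the series design, the line carries a Cre recombinase and a landing pad, a fixed acceptor site for cassette exchange, within AXIN2 on chromosome 17. A plasmid library of barcoded sequences was exchanged into that site by electroporation and the barcodes were sequenced from mRNA and from genomic DNA (gDNA). The labels give 1 group of 5 mRNA libraries, replicates 1 to 5, and do not say whether these came from separate cultures. The p-values of tests over libraries therefore measure the spread between these libraries, which may be technical. Tests that permute class labels or compare counts of calls rest on differences between sequences. Permutation of barcodes rests on differences between barcodes.

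The authors' deposited table holds read counts per barcode, with 5 mRNA columns, 5 gDNA columns and the name of the sequence each barcode belongs to. The deposited read lists hold the 12-base barcode of each mRNA read. For all 148649 listed barcodes, in each of the 5 replicates, the mRNA count in the table equalled the number of reads carrying the reverse complement of the barcode in that replicate's read list, so the table and the read lists gave the same mRNA counts. How barcodes were assigned to sequences, filtered or merged is not given in the sources used here. No molecular identifiers are named, so reads are not counts of molecules. A row of the table for reads with no listed barcode was left out of all tests and library sizes. It held 24.4% to 25.3% of the mRNA reads and 28.8% to 29.4% of the gDNA reads.

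The gDNA columns have no sample of their own in the labels and were joined to the mRNA replicate of the same number. This join rests on the column names. Across barcodes, each of the 5 mRNA libraries correlated best with the gDNA library of its own number, but by a small margin (r 0.205 to 0.234, against 0.191 to 0.228 for other numbers). Across sequences, deviations of same-numbered libraries from the mean of their kind correlated at −0.04 to 0.16, and 0 of 5 mRNA libraries matched their own number best. Alternatives without the join were therefore run.

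Reads were summed over the barcodes of a sequence in each replicate. Activity was log2 of summed mRNA reads plus 1 over summed gDNA reads plus 1, minus the median of the shuffled controls in the same replicate. The design fixed before the data were examined called for sequences that the files name as negative or inactive controls. The files name 5 shuffled versions of generated sequences, and a sequence called wt_enh_del that could be read as a control as well. Taking the 5 shuffled sequences alone was settled after activities per sequence had been seen, and results with wt_enh_del alone and with all 6 as controls are given with the other alternatives.

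The main test of a sequence against the controls was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) of mRNA against gDNA counts over 10 libraries. Offsets set the median control to no difference, no covariate was used, and Benjamini-Hochberg adjustment covered the 101 sequences that are not shuffled controls, at an adjusted p of 0.05. The earlier design named this test for the case of gDNA counts per replicate. Altogether 21 other fits were made, among them limma 3.58.1 and DESeq2 1.42.0, and none replaced the main one. On 20 simulated data sets of 101 sequences with the real depths and fitted dispersions, the edgeR step called 100% of sequences changed by a log2 of 1, 95.8% of those raised by 0.5, 96.7% of those lowered by 0.5 and 1.20% of unchanged ones. The simulation holds the error of the controls at the fitted dispersion and leaves out differences between control sequences.

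Classes were read from the sequence names. Class differences were differences of class medians per replicate, with the mean and SD over 5 replicates and an exact two-sided sign-flip test, whose smallest possible p is 2 in 32. A two-sided permutation of class labels over sequences was exact where a class held under 10 sequences and used 100000 resamples otherwise, with Benjamini-Hochberg adjustment within each family of comparisons. Pairs of sequences were compared by a two-sided permutation of their barcodes, with 100000 resamples and a smallest possible p of 1e-05, adjusted over 12 pairs. On simulated classes of 5 and 20 sequences the exact label permutation called 4.50% of 200 unshifted and 99.5% of 200 classes shifted by 3 SD. Both simulated classes had the same SD, unlike the 5 controls (SD 0.16) and the 15 genomic windows (SD 1.70). The simulation therefore does not give the power of the class tests made here.

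Most sequences named in the text follow a rule fixed before the data were examined: the 10 highest and 10 lowest past the threshold with at least 5 barcodes and the same direction in 5 of 5 replicates, the 3 highest and 3 lowest of each class by the same rule, and the single control or reference sequences. Sequences 31433 and 75119 lie outside this rule and are named because their shuffled versions are among the controls, a choice made after the names had been seen. Alternatives set before the data were examined left out each replicate, required other numbers of barcodes or at least 10 gDNA reads per barcode, took the median over barcodes, centred on library totals or on the median of all sequences, used pseudocounts of 0.5 and 5, left out the top 1% of barcodes, and used limma, DESeq2 or class means. Comparisons of pairs, Fisher's exact tests, the bootstrap over barcodes (1000 resamples), the replicate block, other control sets, gDNA summed over replicates, mRNA without gDNA, removal of mRNA counts of 1 or 2 and the share of barcodes with mRNA were added after the names or values had been seen. The planned test of GC content and motifs was not run, because the sequences themselves were not used here. No build is named for the coordinates in the names of genomic windows, so windows are given only by those names, without annotation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.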

Results

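The library held 106 sequences carried by 148649 barcodes, with 83 to 8636 barcodes per sequence and a median of 1099. By their names, 60 sequences were generated for GM12878, a B lymphoblastoid line, 10 for HepG2, a liver cancer line, and 10 for K562, an erythroleukemia line. A further 15 were named by genomic windows, 5 were shuffled versions of generated GM12878 sequences, 3 had names that begin with wt_ and list further elements, and 1 each was named wt_enh_del, ref and alt. What ref, alt and wt_enh_del stand for is not given in the sources used here. Reads with a listed barcode numbered 3930449 to 4435725 per mRNA library and 3642970 to 4373042 per gDNA library. Per library, 18386 to 22728 barcodes had mRNA reads, with a median of 119 to 160 reads each, and 86505 to 95407 had gDNA reads, with a median of 23 to 31.

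The first question was which sequences, placed within AXIN2 in these B leukemia cells, gave more or less barcode mRNA per gDNA than shuffled DNA. Of 101 sequences, 41 lay above the shuffled controls and 12 below them. The 41 comprised 25 of 60 generated GM12878 sequences, 10 of 15 genomic windows, 2 of 10 generated HepG2 sequences, all 3 wt_ combinations and alt. The HepG2 calls did not hold in every fit. Sequence 91942 (edgeR adjusted p = 0.0442) was lost without replicate 1, 2 or 4 and with limma (adjusted p = 0.125). It was also lost with the replicate block in edgeR (adjusted p = 0.131) and with gDNA summed over replicates (limma adjusted p = 0.0605). Sequence 43258 was lost without the top 1% of barcodes (edgeR adjusted p = 0.157). A bootstrap over barcodes called 0 of the 10, against 23 of 60 GM12878 sequences. Generated K562 sequences gave 0 calls of 10 with edgeR, limma or DESeq2, and 0 had an unadjusted edgeR p under 0.05. They had fewer barcodes, with a median of 349 against 1216.5 for GM12878, so small effects were harder to call. Of the 12 below, 10 were generated for GM12878 and 2 were genomic windows. Calls came from edgeR's quasi-likelihood test at an adjusted p of 0.05, and many were small: 22 of the 41 were above 2-fold and, by mean activity, 3 of the 12 were below by more than 2-fold. By the fold that edgeR fitted the latter count was 2, and it was 1 without replicate 2 or without replicate 4, 30 with library totals and 0 to 3 in the remaining fits. The 5 shuffled controls themselves ranged from −0.16 to 0.28 (log2), and 8 of the 41, with both HepG2 sequences among them, did not exceed the highest control. The split of calls rests on where zero is set: centring on library totals gave 21 above and 77 below, with a median shift of −0.97 (log2), and centring on the median of all sequences gave 34 above and 21 below, with a shift of −0.12.

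**Figure D1:**
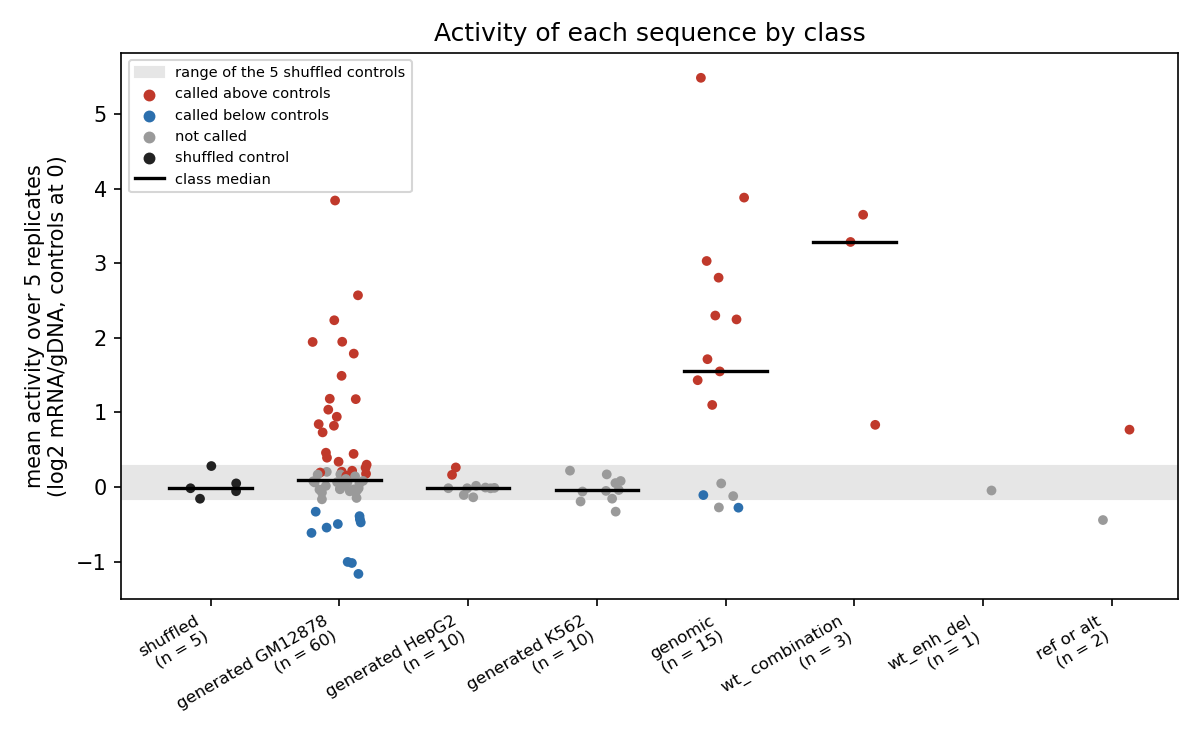
Mean activity over 5 replicates (log2 mRNA over gDNA, shuffled controls at 0) for each of the 106 sequences, by class, with class medians as bars and the range of the 5 shuffled controls, −0.16 to 0.28, shaded. Generated HepG2 and K562 sequences lie in or near the shaded range, while generated GM12878 sequences run from −1.16 to 3.84 and genomic windows from −0.28 to 5.49.

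The highest sequence was the genomic window chr22:22935643-22935843, with an activity of 5.49 ± 0.29 (SD, n = 5), 44.8-fold above the controls, on 83 barcodes. Its 5 barcodes with most mRNA reads held 57.2% of its mRNA reads, and without them its activity was 4.80. The window chr7:26156429-26156629 followed at 3.88 ± 0.07, or 14.7-fold, on 1581 barcodes, and the window chr2:6345656-6345856 reached 3.03 ± 0.07, or 8.17-fold. Among generated sequences, GM12878 sequence 72365 was highest at 3.84 ± 0.16, or 14.3-fold, ahead of 82895 at 2.57 ± 0.06 and 82101 at 2.24 ± 0.09. The combinations wt_MF2A_SPI1_FX1_BH1 and wt_MF2A_SPI1_FX1_TF65 reached 3.65 ± 0.10 and 3.28 ± 0.07. SPI1 is the gene of PU.1, a transcription factor of B cells and myeloid cells, and what the other parts of these names denote is not stated. The remaining combination, wt_MF2A_PU1_MF2A, names PU1 as well and was lower, at 0.83 ± 0.15. Each of the other 8 was above 0 in 5 of 5 replicates, with edgeR adjusted p-values from 5.65e-25 to 6.76e-17. With the median over barcodes these 8 ran from 0.998 for 82101 to 7.56 for chr22:22935643-22935843, and with the share of barcodes with mRNA from 1.42 to 2.37 for the same sequences.

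At the low end, GM12878 sequence 98304 was lowest at −1.16 ± 0.21 (SD, n = 5), 2.24-fold below the controls, followed by 61018 at −1.02 ± 0.29 and 99984 at −1.004 ± 0.08. The other 7 of the 10 lowest, all generated for GM12878, lay between −0.62 and −0.33. The genomic window chr1:186102643-186102843 was at −0.28 ± 0.17. These 11 were below 0 in 5 of 5 replicates and lay under every shuffled control, with edgeR adjusted p-values from 1.72e-15 to 0.0056. With the median over barcodes, tested with limma, 98304, 61018 and 99984 stayed below at −0.21, −0.16 and −0.17. The calls of 12590, 39615, 71280, 34745, 77339 and the chr1 window were lost, at −0.11 to −0.0022 (limma adjusted p from 0.0597 to 0.984). In any replicate, at most 18.4% of barcodes with at least 10 gDNA reads had mRNA in these sequences and the controls. Their median barcode thus had none, so neither outcome tests their mRNA. The chr1 window also lost its call with at least 10 gDNA reads per barcode (edgeR adjusted p = 0.0816).

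**Figure D2:**
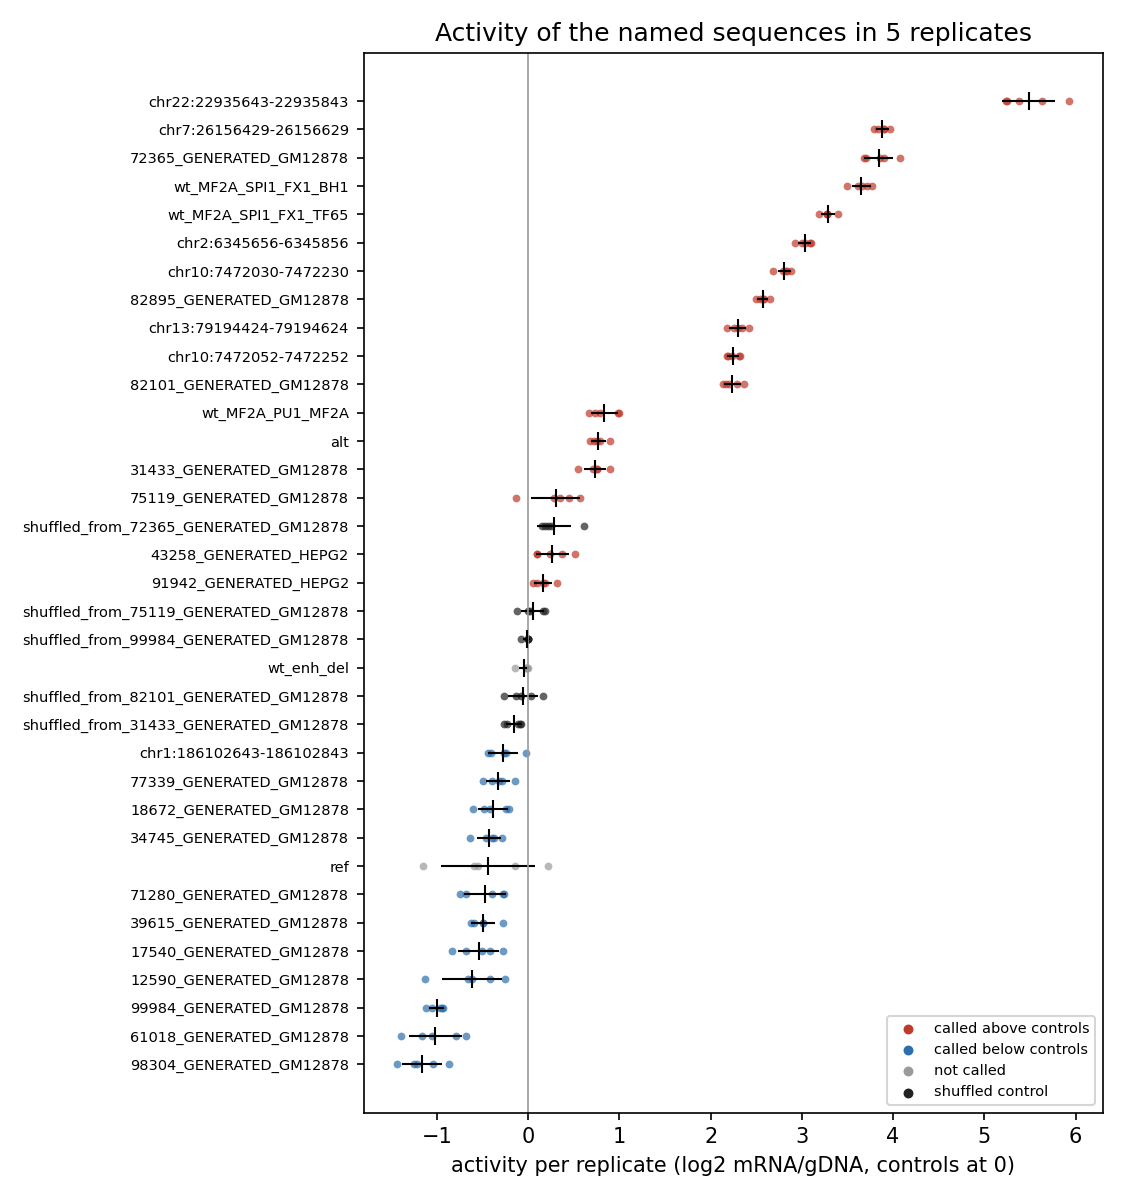
Activity of the named sequences (log2 mRNA over gDNA, shuffled controls at 0): points are the 5 replicates, bars the mean and SD. Sequence names are on the vertical axis in order of mean activity, from 98304 at −1.16 to chr22:22935643-22935843 at 5.49, and ref spreads widest, with an SD of 0.51.

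Classes were then compared with the shuffled controls. The median genomic window was 1.54 ± 0.12 (SD, n = 5) above the median control, or 2.91-fold, in 5 of 5 replicates, but 1.07 above with the share of barcodes with mRNA. With the median over barcodes it was 0.46 above, where the median barcode of the controls had no mRNA. The median of generated GM12878 sequences differed from the median control by 0.11 ± 0.07, that of HepG2 sequences by 0.02 ± 0.10 and that of K562 sequences by −0.02 ± 0.09. Sequences within the GM12878 and genomic classes ranged on both sides of the controls. Over sequences, exact label permutation gave p = 0.211 for genomic windows, 0.485 for GM12878, 0.820 for HepG2 and 0.770 for K562, each with an adjusted p of 0.820, so no class median was separated from the 5 controls. The power of this test for classes of unequal spread was not measured. With 5 replicates an exact sign-flip test cannot pass a p of 0.05, since 2 of 32 sign patterns have all signs alike, and HepG2 and K562 differences had mixed signs (exact p = 0.625).

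Whether sequences made for a B cell line were more active in these B leukemia cells than those made for other lines was asked of the generated classes. The median GM12878 sequence exceeded the median HepG2 sequence by 0.09 ± 0.11 (SD, n = 5), in 4 of 5 replicates, and the median K562 sequence by 0.14 ± 0.06, in 5 of 5. HepG2 and K562 medians differed by 0.04 ± 0.11. Label permutation over sequences gave p = 0.282, 0.160 and 0.318, each with an adjusted p of 0.318, so class medians were not separated. In counts, chosen for testing after they had been seen, 25 of 60 GM12878 sequences were called above the controls against 2 of 20 for HepG2 and K562 together (Fisher's exact test, two-sided, p = 0.0128, adjusted p = 0.0383 over 6 tests). This call was lost without replicate 4 (Fisher's exact adjusted p = 0.0505) and with centring on library totals (adjusted p = 0.123), and it passed in 19 of 21 other fits. Calls also depend on precision: the median number of barcodes was 349 for K562 sequences, 894.5 for HepG2 and 1216.5 for GM12878. K562 sequence 56191, at 0.22 on 309 barcodes, was not called, while GM12878 sequence 82375, at 0.22 on 3834, was. The counts called therefore do not measure activity alone. Above 2-fold the counts were 10 of 60 and 0 of 20 (Fisher's exact p = 0.0590, adjusted p = 0.0885). Genomic windows passed 2-fold more often than generated GM12878 sequences, in 10 of 15 against 10 of 60 (Fisher's exact adjusted p = 0.0019, and 0.0010 to 0.0336 over 21 other fits), while how either set was picked is not given in the sources used here. Those 10 windows include the overlapping pair on chromosome 10 compared below, which the test counts as separate sequences.

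Comparing 5 generated GM12878 sequences with their own shuffled versions, 3 were higher, 1 was lower and 1 was not separated. Sequence 72365 exceeded its shuffled version by 3.56 ± 0.22 (log2, SD, n = 5), or 11.8-fold, sequence 82101 by 2.29 ± 0.22, or 4.90-fold, and sequence 31433 by 0.89 ± 0.18, or 1.85-fold. Sequence 99984 lay below its shuffled version, with a difference of −0.99 ± 0.10. That shuffled version was itself the median control in replicates 2 to 5, so this nearly repeats the comparison of 99984 with the controls. Each of these 4 differences had the same sign in 5 of 5 replicates and a barcode permutation p of 1e-05, the smallest that the resamples allow (adjusted p = 1.5e-05). With the median over barcodes the differences were 5.098 for 72365, 0.94 for 82101, 0.25 for 31433 and −0.12 for 99984, and with the share of barcodes with mRNA 1.87, 1.40, 0.49 and −0.65. Of barcodes with at least 10 gDNA reads, 37.5% of 82101, 19.6% of 31433 and 8.08% of 99984 had mRNA. The median barcode of these had none, so the median over barcodes says little of their mRNA. Sequence 75119 differed by 0.25 ± 0.15, in 4 of 5 replicates, with a barcode permutation p of 0.0627 (adjusted p = 0.0684). Without replicate 5 its adjusted permutation p was 0.0384, at a difference of 0.32. Against the controls as a set, 75119 lost its call without replicate 2 (edgeR adjusted p = 0.0626), without replicate 4 (0.0552) and with the median of all sequences as the centre (0.0707).

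**Figure D3:**
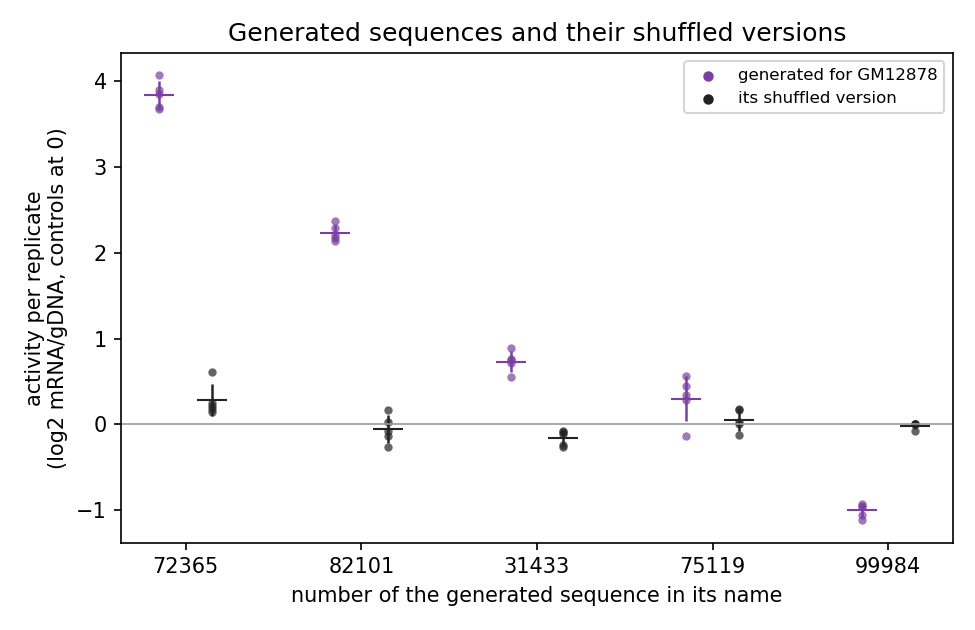
Activity (log2 mRNA over gDNA, shuffled controls at 0) of 5 generated GM12878 sequences and of their shuffled versions: points are the 5 replicates, bars the mean and SD. Replicates of 72365, 82101 and 31433 lie above those of their shuffled versions, those of 99984 below, and those of 75119 overlap.

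Among the single named sequences, alt exceeded ref by 1.21 ± 0.45 (log2, SD, n = 5), or 2.32-fold, in 5 of 5 replicates (barcode permutation p = 0.0039, adjusted p = 0.0046). The ref sequence had 172 barcodes and an activity of −0.44 ± 0.51, not separated from the controls in the main test (edgeR adjusted p = 0.214), while alt had 1854 barcodes and 0.77 ± 0.08. The ref sequence was called below the controls with limma (adjusted p = 0.0367), with the replicate block in edgeR (adjusted p = 0.0389), without replicate 4 (edgeR adjusted p = 0.0335) and with library totals. The sequence wt_enh_del, with 8636 barcodes, was at −0.04 ± 0.06 (edgeR adjusted p = 0.109), but was called below with the median of all sequences as the centre (−0.16, edgeR adjusted p = 1.36e-04) and with library totals (−1.01). Relative to wt_enh_del, wt_MF2A_SPI1_FX1_BH1 was higher by 3.69 ± 0.11, wt_MF2A_SPI1_FX1_TF65 by 3.33 ± 0.10 and wt_MF2A_PU1_MF2A by 0.88 ± 0.12, each with a barcode permutation p of 1e-05. The difference of ref from wt_enh_del was −0.40 ± 0.48 (permutation p = 0.253). With the median over barcodes in place of summed reads, alt minus ref was 0.13 and alt was no longer called above the controls (limma adjusted p = 0.129). The differences from wt_enh_del were 0.20 for wt_MF2A_PU1_MF2A, 4.85 for wt_MF2A_SPI1_FX1_BH1 and 3.21 for wt_MF2A_SPI1_FX1_TF65. With the share of barcodes with mRNA these differences were 0.53, 2.10 and 1.93. By that share alt stayed above the controls at 0.66 (limma adjusted p = 3.02e-21). Of barcodes with at least 10 gDNA reads, 22.2% of alt, 14.4% of ref, 19.5% of wt_MF2A_PU1_MF2A and 13.5% of wt_enh_del had mRNA. Their median barcode thus had none, so the median over barcodes says little of their mRNA.

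A pair of overlapping genomic windows on chromosome 10 differed in activity. The window chr10:7472030-7472230 was at 2.81 ± 0.07 and chr10:7472052-7472252 at 2.25 ± 0.07 (SD, n = 5). The first exceeded the second by 0.56 ± 0.09, or 1.47-fold, in 5 of 5 replicates (barcode permutation p = 8e-05, adjusted p = 1.07e-04). The difference was 0.39 without gDNA, 0.23 with the share of barcodes with mRNA and 0.70 with the median over barcodes, none of them tested.

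Activities were compared between replicates to show the error behind each value. Across the 106 sequences, the 10 pairs of replicates had Pearson correlations of 0.958 to 0.974 and Spearman correlations of 0.726 to 0.846. These are across sequences within a pair of libraries and describe the assay, since sequences are not replicates. The median SD over replicates was 0.16 (log2), with a range of 0.02 to 0.84. Barcodes of each sequence split at random into 2 sets gave activities that correlated at a median r of 0.971 (Spearman 0.780) over 20 splits. Single barcodes of a sequence with mRNA reads and at least 10 gDNA reads varied with a median SD of 2.36 (log2). PCR reads without molecular identifiers are not independent molecules.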

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

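Of 58 values looked at for 1 library far from the others, 4 stood out, against 2.90 by chance. The activity of the shuffled version of 72365 was 0.61 in replicate 1 against 0.15 to 0.25 in the other 4, a gap of 0.782 of its range. The shuffled version of 99984 was at −0.08 in replicate 1 and at 0 in the others, a gap of 1.00 of its range, because it was itself the median control, set to 0, in those 4. The sequence wt_enh_del was at −0.14 in replicate 1 against −0.03 or closer to 0 elsewhere, a gap of 0.790. The median control of replicate 1 was the shuffled version of 75119, so part of this gap follows from the change of zero. Barcodes with mRNA reads numbered 18386 in replicate 3 against 21823 to 22728 in the others, a gap of 0.792.

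Reads outside the main measurement were common: 25.0% of mRNA reads (mean of 5 libraries, SD 0.328) carried no listed barcode. Of these reads, 50.04% lay within 1 mismatch of a listed barcode, against 17.1% for the same search in the opposite orientation.

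The tests on removed or few barcodes and gDNA depth in the next 3 paragraphs were set before their results were seen. The count with each barcode counted once, the count under every control at matched gDNA depth and the Fisher test on cell line of design were chosen afterwards.

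Sequences below the shuffled controls, 12 of them, were weighed against technical explanations. When each barcode counted once, as with or without mRNA, 11 of the 12 stayed below (limma). For those 11, a few barcodes with most of the reads are argued against as the whole account. That count was chosen afterwards and uses the reads that picked the 12, so it does not test chance. Without the top 1% of barcodes 11 of the 12 kept their call. Other values leave an effect of a few barcodes undecided. The median of the 12 without those barcodes was −0.50, which sets sequences picked as low against single controls (SD 0.137). With the median over barcodes 5 stayed below and 7 were at −0.11 to −0.0022, where at most 18.4% of barcodes had mRNA and the median barcode had none. Among barcodes with 10 to 50 gDNA reads, the median share with mRNA was 7.17% (4.78% to 9.23%) for the 12 and 9.48% (8.57% to 12.5%) for the controls. The ratio was 0.757 (0.609 to 0.856 over replicates), and 11 of the 12 lay under every control. Depth per barcode alone would leave these shares alike, so for those 11 it is argued against as the whole account. The 12 were picked as low from the same reads, so the gap was not tested against chance. Open are design for GM12878, the centring (21 below with the median of all at 0) and a repressing effect, which may exist as a hypothesis and was not tested. On design, 10 of 60 GM12878 and 0 of 20 HepG2 and K562 sequences were below (Fisher exact p of 0.0590). The difference was 25.0 percentage points for the share of barcodes with mRNA (Fisher exact adjusted p of 0.0273). With library totals, which put 77 sequences below, it was −20.0. Few barcodes limit the 0 of 20. K562 sequence 92295, at −0.33 on 83 barcodes, was not called, while GM12878 sequence 77339, at −0.33 on 1702, was.

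The highest sequence, chr22:22935643-22935843, stood apart on 83 barcodes. Its 5 barcodes with most mRNA reads held 57.2% of its mRNA reads, yet without them its activity was 4.80 (4.46 to 5.52 over replicates), above the next highest sequence at 3.88. With barcodes of at least 10 gDNA reads it was at 5.57, against 3.95 for the next highest, so barcodes lacking gDNA reads did not account for it. The size of its value depends on those 5 barcodes, and no biological explanation was tested.

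For alt above ref, few ref barcodes were weighed. Of 10000 random subsets of alt barcodes of the size of ref, 0% lay at or below the value of ref with reads summed over the 5 replicates (−0.33), the lowest subset, summed alike, being −0.24. This count is one-sided and holds the value of ref fixed, close to the lowest subset. The two-sided permutation of alt and ref barcodes gave a weaker p of 0.0039. Leaving out a replicate, the permutation p ran from 3e-04 (without replicate 4) to 0.0251 (without replicate 1). It was 0.0202 with at least 10 gDNA reads and 2e-04 without the top 1% of barcodes. Chance draws of barcodes are thus less likely as the whole account of the difference, but not excluded. What distinguishes the sequences was not used here, and no biological explanation was tested.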

How the results depend on the processing

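The control sets, the replicate block, summed gDNA, mRNA without gDNA, the share of barcodes with mRNA, removal of mRNA counts of 1 or 2 and the bootstrap were chosen after seeing the data, as were all comparisons of pairs. Sequencing depth was not varied in these settings. Over 21 other fits the number of sequences called ran from 35 to 98, against 53, and the number above 2-fold stayed at 20 or more except with library totals (11), the median over barcodes (8) and the share of barcodes with mRNA (17). Leaving out 1 replicate at a time gave 47 to 57 called sequences, 35 to 40 above and 11 to 17 below. limma called 40 above and 12 below, DESeq2 41 and 12, the bootstrap over barcodes 37 and 11. With wt_enh_del as the control, 45 were above and 11 below, and with the shuffled sequences and wt_enh_del together 41 and 11. Numbers do not pair the mRNA and gDNA libraries across sequences, and with the replicate block 40 were above and 13 below. Minimums of 1, 10 and 20 barcodes removed no sequence, and the read lists gave the same mRNA counts, so those settings could not change a value. GC content and motifs were not run, and molecules could not be counted.

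Centring on library totals called 98, 21 above and 77 below, and turned wt_MF2A_PU1_MF2A to −0.14, alt to −0.20, 31433 to −0.24, 75119 to −0.66, and HepG2 sequences 43258 and 91942 to −0.70 and −0.81. This follows from the construction, since the reads of highly active sequences raise the total. Centring on the median of all sequences called 21 below. The median over barcodes called 35, 7 of them below. For the remaining changes the cause was not tested.

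None of the class differences passed the threshold in any setting, and those near 0 changed sign. With the median over barcodes, GM12878 minus shuffled was −0.020, HepG2 minus shuffled −0.038, GM12878 minus K562 −0.0061 and HepG2 minus K562 −0.024. The median barcode of the controls and of most generated sequences had no mRNA, so these values say little of activity. With the share of barcodes with mRNA, HepG2 minus shuffled was −0.034, K562 minus shuffled 0.044, GM12878 minus K562 −0.012 and HepG2 minus K562 −0.078. HepG2 minus shuffled was −0.026 without gDNA and −0.0071 with class means. K562 minus shuffled was 0.038 with at least 10 gDNA reads and 0.019 against wt_enh_del. Leaving out a replicate, K562 minus shuffled ran from −0.047 to 0.0087 and HepG2 minus K562 from −0.0039 to 0.066.

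Differences of generated sequences from their shuffled versions kept their sign but moved. With the median over barcodes they were 0.25 for 31433, 5.098 for 72365, 0.94 for 82101 and −0.12 for 99984, and alt minus ref 0.13. With the share of barcodes with mRNA they were 0.49, 1.87, 1.40 and −0.65, and alt minus ref 0.65. The median barcode of 31433, 82101, 99984, alt, ref and the shuffled versions had no mRNA, so the median over barcodes says little there. Without gDNA 31433 differed by 0.60. For 75119, leaving out a replicate gave 0.21 to 0.32, and the difference passed the permutation threshold without replicate 5 and without the top 1% of barcodes (0.27).

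Sequence 43258 was at −0.026 with the median over barcodes, where its median barcode had no mRNA. Further, wt_enh_del was at 0.0062 with at least 10 gDNA reads and ref at 0.015 with the share of barcodes with mRNA. The median correlation of replicates was 0.955 with at least 10 gDNA reads, 0.985 with the median over barcodes and 0.939 with the share of barcodes with mRNA, against 0.964. Most sequences had no mRNA in their median barcode, so 0.985 says little of the agreement of their mRNA.

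Fisher tests of shares, as percentage points, moved as follows. GM12878 minus HepG2 and K562 in the share above was 15.0 with library totals, and 28.3 to 33.3 when a replicate was left out, losing the call without replicate 4. In the share below, the same difference was −20.0 with library totals and 25.0 with the share of barcodes with mRNA, both past the threshold. Genomic minus GM12878 in the share above passed at 51.7 with library totals, 35.0 with the median of all sequences, 41.7 with the median over barcodes and 35.0 with the share of barcodes with mRNA, and in the share below at −46.7 with library totals.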

Other observations

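The tests of spread and of the parts of activity in this part were chosen after the results had been seen, and the splits of libraries were set before.

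Generated GM12878 sequences differed among themselves far more than those made for the other lines. Their mean activities had an SD over sequences of 0.88 (n = 60), against 0.14 (n = 20) for HepG2 and K562 sequences together. Permutation of the median-centred values gave a two-sided p of 9.9e-04 for this difference of SDs. The test measures the spread that prompted it and says nothing of direction. Design for GM12878 and the way the sequences of each class were picked, which is not given in the sources used here, cannot be told apart as sources of the spread.

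Activity was made of more than 1 part. Across the 106 sequences, the share of gDNA-supported barcodes with any mRNA correlated with activity at a Spearman rho of 0.898, and the mean mRNA reads per barcode with mRNA at 0.866. Both are built from the same reads as activity, so some correlation follows from the construction. The share ran from 72.3% for chr22:22935643-22935843 to 7.22% for 98304, and was 13.5% for wt_enh_del. Number of barcodes had a Spearman correlation with activity of 0.123 across sequences, which are not independent replicates.

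For the 53 sequences called, other groupings of the libraries were tried. Of 100 splits of the 10 libraries into 5 and 5, only the real split of mRNA against gDNA called as many (1 split), and the highest of the others called 0. Every other split mixes mRNA and gDNA libraries in both arms, which widens the spread within arms, so the 0 calls there exclude nothing about the single calls.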
